A study of Mus musculus with 24 samples.

How the data were processed

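Mouse 32D cells, an IL-3-dependent line from bone marrow, were measured by RNA sequencing of polyadenylated RNA during treatment with actinomycin D, an inhibitor of transcription. The labels gave 3 genotypes, wild type (WT) and 2 clones labelled Nat10+/- (KO1 and KO2). Each genotype was sampled at 0, 3, 6 and 9 h of actinomycin D at 0.05 µg/ml, with 2 libraries per genotype and time, so that 24 libraries fell into 12 groups. Per the labels' protocols, cells grew with 10% serum and IL-3 at 10 ng/ml, an equal amount of ERCC spike-in RNA was added to each total RNA sample, and libraries were made with a directional kit. The group of every library was taken from its title.

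The values were counts of read pairs per gene as deposited by the authors, one table per library. Per the file headers, the authors made them with featureCounts 1.6.3 in paired-end mode over exons grouped by gene, without use of strand, on an annotation path naming Ensembl release 105 of GRCm39 joined to the ERCC sequences. The submitters' processing notes also named STAR and DESeq2, whose versions were not given in the sources used here. The tables listed 55414 gene identifiers and 92 spike-in transcripts, with 0 entries that named no gene. Because the kit kept strand and the counting did not, reads of overlapping and antisense genes could not be told apart. Near-identical family members, such as those of the Oas, Ifit, Mx, Gbp, histone and Lilrb4 families, could share or lose reads. Gene names came from a GENCODE mouse table, release M21, which named 52081 of the identifiers. Coordinates are those in the files, on GRCm39, from the first to the last exon of a gene.

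Depth ran from 15361601 to 17338939 gene counts per library. The counts carry no molecular identifiers, so bounds and counting intervals (95%, exact) cover counting error only. A gene with 0 counts over both libraries of a group was given a floor of 3 counts over the group, and folds against it are lower bounds.

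Genes were kept with filterByExpr in edgeR 4.0.16 at a minimum count of 10, which left 16167. Libraries were scaled by TMM. One quasi-likelihood model with a coefficient for each of the 12 groups gave the differences between genotypes and times. A second model with an intercept and a slope over hours for each genotype gave differences of slopes, in log2 units per hour. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the adjusted p-values below come from these edgeR tests unless another tool is named. Fold changes fitted by edgeR are given as log2 values with their standard errors (SE). Levels are CPM on the TMM scale as mean ± SD of 2 libraries.

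A rule fixed before the data were examined asked for at least 1000 spike-in counts in every library before spike-ins could set the scale. The WT libraries held between 120 and 257, so TMM was used throughout. A slope is therefore relative to the average transcript, not an absolute decay rate. It can also hold gain of a transcript as well as loss. Even with spike-in totals as the scale, 2066 genes in KO2 and 4583 in KO1 were called at least 2-fold higher at 9 h than at 0 h. For the median slope, a least-squares line was fitted per gene and replicate series to log2 CPM with a prior count of 0.5, over the 10254 genes with a mean of at least 5 CPM. The 4 KO series were compared with the 2 WT series by an exact two-sided permutation test over 15 splits, whose smallest possible p is 0.133.

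The 26 gene lists, the models, the scaling rule, the alternatives and the rule for naming genes were chosen before the data were examined. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a list move on balance one way. They covered ribosomal proteins, ribosome biogenesis, p53 targets, G1/S, G2/M, histones, short-lived and long-lived mRNAs, IL-3 and STAT5 response, RNA modification, mRNA decay, snoRNA hosts, metabolism, stress and interferon responses, apoptosis, and markers of blood and stromal cells. Of the 42 histone genes fixed, 20 matched a name and 12 were tested. Genes named below are Nat10, the 8 largest rises and 8 largest falls called in both clones, the 4 largest each way in the other comparisons, and up to 2 members each way of every list. All of these needed a mean of at least 5 CPM, except list members, and predicted genes were not named. Genes named outside that rule are said to be so.

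The pairs of libraries were compared before they were averaged. They differed by more than sampling noise in all 12 groups (chi-square per degree of freedom between 1.45 and 2.37), so they were not merged. Repeat preparations of 1 culture could differ in the same way, so this does not show that the libraries are independent. The labels call them biological replicates, but they do not say that cultures were grown and treated separately. The p-values measure the spread between these libraries, which may be partly technical. Each clone has its own coefficient, so the spread between clones does not enter the edgeR, camera and fry p-values. Scripts were tested on simulated counts for the 16167 genes. At 2-fold, 82% of 50 changed genes were recovered for KO1 against WT at 0 h, with 3 false calls. For slopes of both clones against WT, 82% of 50 were recovered when the difference reached 2-fold over the course, with 3 false calls. Those simulated courses were otherwise flat, and each library varied on its own with the spread of the model with 12 groups. The biological coefficient of variation was 0.0206 in that model and 0.257 around straight lines. The simulated slope rates therefore do not carry over to the slopes of the data.

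Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, the 0 h libraries alone, the replicate number as a block, each replicate left out, the change from 0 h to 9 h in place of the line, the courses without 0 h or 9 h, and for the median slope a minimum of 1 or 20 CPM. Where a replicate was left out of the model with 12 groups, the lone library was assumed to vary like those of the other groups. Alternatives chosen after the data had been seen were spike-in totals as the scale, summed replicate pairs, a time course common to all genotypes with a slope difference per clone, and the genotype difference over all 4 times. R was version 4.3.3. Spike-in scaling was not run for the 0 h comparisons because the rule above was not met, and absolute half-lives are not reported as results for the same reason.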

Results

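The series asked whether Nat10, the enzyme that acetylates cytidine in RNA to ac4C, affects how long mRNAs last in 32D cells. Counts per gene were available for 24 libraries, 2 for each of WT, KO1 and KO2 at 0, 3, 6 and 9 h of actinomycin D, an inhibitor of transcription that at low doses acts mainly on RNA polymerase I. Each library held between 15361601 and 17338939 gene counts, so depth was close to even across groups.

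Replicate libraries were very similar. The median absolute log2 difference between the libraries of a pair lay between 0.06 and 0.07, against 0.10 between KO1 and KO2 at 0 h and 0.13 between either clone and WT. The pair values compare single libraries and the others compare means of 2 libraries, which carry less noise, so these are unlike measures. The biological coefficient of variation was 0.0206 in the model with 12 groups and 0.257 around straight lines over time. Spike-in RNA differed far more between genotypes than the added amounts stated in the labels. WT libraries of 0 h held 7.19 ± 0.38 spike-in CPM, relative to gene counts (SD, n = 2), KO1 240.4 ± 0.29 and KO2 332.9 ± 12.9. At matched times the WT value was 18.4 to 62.6-fold below those of the clones.

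**Figure D1:**
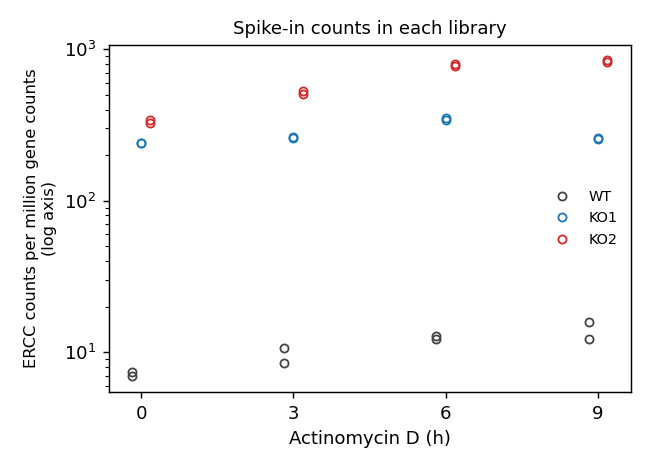
Spike-in CPM, relative to gene counts (log axis), against hours of actinomycin D, 1 point per library. At 0 h WT sat near 7.19, KO1 near 240.4 and KO2 near 332.9, and the 2 libraries of each pair lay close together.

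Nat10 mRNA was slightly lower in both clones. Nat10 (ENSMUSG00000027185, chromosome 2, 103551601 to 103591615) stood at 112.1 ± 1.52 CPM in WT (SD, n = 2), 103.1 ± 7.62 in KO1 and 97.18 ± 2.87 in KO2 at 0 h. The fitted difference over both clones was -0.16 (log2, SE 0.04, adjusted p = 0.000801, edgeR), which is 1.12-fold lower. In KO2 it was -0.21 (SE 0.05, adjusted p = 0.000291) and in KO1 -0.12 (SE 0.05, adjusted p = 0.0486). The KO1 call was lost with DESeq2 (adjusted p = 0.121), with no filter (0.0755), with the 0 h libraries alone (0.0724) and without WT replicate 1 (0.0913), WT replicate 2 (0.212) or KO1 replicate 1 (0.635). Counts over the whole gene do not show how much functional protein each clone makes.

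Before the drug, both clones had less mRNA than WT for the receptors Lilrb4a, Lilr4b and Il18r1 and for members of the glycolysis list. Lilrb4a (chromosome 10, 51367052 to 51372707) and its neighbour Lilr4b (51356728 to 51362799), genes of the leukocyte immunoglobulin-like receptor family, fell from 132.8 ± 2.08 and 90.89 ± 2.13 CPM in WT to 24.9 ± 2.57 and 13.32 ± 0.30 in KO1, and to 21.66 ± 0.56 and 12.39 ± 0.63 in KO2 (SD, n = 2). Il18r1 (chromosome 1, 40504712 to 40540014), a subunit of the interleukin-18 receptor, was 8.99-fold lower over both clones by its counts. Klhl6 (chromosome 16, 19765246 to 19801787), an adaptor of a ubiquitin ligase, rose from 0.80 CPM in WT to 8.84 in KO1 and 10.46 in KO2. Hbb-bs, an adult beta-globin gene, rose from 0.15 to 2.29 and 8.49 CPM.

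In the model, 5102 of 16167 genes differed between both clones and WT at 0 h, 2706 higher and 2396 lower. Spread between clones does not enter this test or the list tests below. The calls therefore describe these clones and these WT cells, and need not be effects of the genotype. KO1 alone gave 4416 calls (2433 higher) and KO2 alone 4747 (2438 higher). The number at least 2-fold lower was 340 over both clones, against 151 at least 2-fold higher. In both clones in the same direction, 1447 genes were higher and 1256 lower, and 152 were called in opposite directions. Independent lists of these sizes would share 366.9 and 283.2. The log2 differences of the clones correlated across genes at r = 0.532. Unchanged groups simulated with WT libraries in common gave 0.481, so part of this correlation may come from the shared controls. The simulated clones shared 0 calls in the same direction. Each simulated library varied on its own, however, so a shift common to both WT libraries could still add to the overlap. The covariance was 0.393 against 0.147 in the simulation, a difference of 0.246. Genes are not independent replicates.

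Other falls in both clones were those of Lyz2, the macrophage lysozyme (log2 -3.04, SE 0.17, adjusted p = 6.86e-31), and Vsir, a checkpoint receptor (-2.21, SE 0.11, adjusted p = 4.03e-33). Ggt1, gamma-glutamyltransferase, rose from 3.84 CPM in WT to 14.55 in KO1 and 11.83 in KO2. Mid1ip1, a regulator of lipid synthesis on chromosome X (10581252 to 10585929), stood at 20.14 ± 2.74 CPM in WT and 9.58 ± 0.42 in KO1. KO2 had 0 counts for it, which makes it at least 215-fold lower than WT. Ahnak (12 counts over both clones, 33 in WT) and Exoc3l2 (5 counts against 14) lay near the floor. The Exoc3l2 call was lost without WT replicate 2 (log2 -2.09). Over all 4 times with pairs summed Exoc3l2 turned higher in the clones (log2 0.717, adjusted p = 0.0224, edgeR). Of the 8 largest rises named, the other 7 were those of Apol9b, Mx2, Ifit1, Plac8, Oas2, Usp18 and Oasl1, whose levels differed widely between the clones. With replicate pairs summed and the genotype difference taken over all 4 times, a setting chosen after the data had been seen, 2161 of the 5102 calls held in the same direction.

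Of the 26 lists, 15 passed camera in both clones against WT at 0 h, 8 higher and 7 lower, and all 15 held with an estimated correlation. In the glycolysis list, 21 of 25 members fell (21 adjusted over the list alone; median log2 -0.37, camera adjusted p = 2.2e-37). Bnip3, a mitophagy receptor induced by low oxygen, went from 119.7 ± 0.33 CPM in WT to 45.63 ± 3.07 in KO1 and 61.93 ± 3.26 in KO2. Egln3, an oxygen-sensing prolyl hydroxylase, went from 77.88 ± 6.64 to 29.34 ± 0.42 and 42.48 ± 1.87. Neither of these is a glycolytic enzyme. Eno1, which is one, went from 998.5 ± 2.08 to 514.6 ± 4.87 and 685.4 ± 2.23. Among long-lived housekeeping mRNAs 31 of 40 fell and 4 rose (33 and 4 adjusted over the list alone; adjusted p = 9.27e-35), with Fth1, the ferritin heavy chain, 1.56-fold lower and B2m, the light chain of MHC class I, 1.32-fold higher. The rise of B2m was that of KO2 (1086 CPM, against 608.5 in WT), while KO1 stood at 596 (adjusted p = 0.293).

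Lists of ribosome biogenesis, G1/S, the integrated stress response, p53 targets and RNA metabolism rose at 0 h. For ribosome biogenesis, 50 of 73 members rose and 1, Nat10 itself, fell (52 and 1 adjusted over the list alone; median 0.16, adjusted p = 1.39e-15), led by Utp20 (1.37-fold) and Nop14 (1.33-fold), both processing factors of the small subunit. Of 40 G1/S genes, 24 rose and 2 fell (27 and 2 adjusted over the list alone; adjusted p = 2.03e-08). Tyms, thymidylate synthase, was 1.38-fold higher, and Exo1, an exonuclease, was 1.19-fold lower. The integrated stress response list had 22 of 32 members higher and 1 lower (23 and 2 adjusted over the list alone; adjusted p = 2.85e-14), with the transcription factors Cebpb 1.57-fold and Atf5 1.51-fold higher. Over all 4 times with pairs summed Cebpb turned lower without passing (log2 -0.589, adjusted p = 0.133, edgeR). Among p53 targets 18 of 37 rose and 3 fell (20 and 4 adjusted over the list alone; adjusted p = 4.76e-05). Aen, a nuclease, rose 1.53-fold, and Ddb2, a DNA damage sensor, fell. For mRNA decay machinery 22 of 48 rose and 3 fell (22 and 4 adjusted over the list alone; adjusted p = 0.00122), including the exosome subunits Exosc8 and Exosc3, each 1.26-fold higher. RNA modification enzymes gave 16 of 33 higher and 3 lower (16 and 4 adjusted over the list alone; adjusted p = 1.12e-05), with Trmt61a 1.46-fold higher and Igf2bp2 1.36-fold lower. Of 15 snoRNA host RNAs, 8 rose (8 adjusted over the list alone; adjusted p = 0.00105), Snhg15 by 1.32-fold. The rise of G1/S genes was limited to 0 h. At 3 h 33 of 40 were lower than in WT in KO1 (0 higher) and 27 in KO2 (2 higher). These falls passed camera with an estimated correlation (adjusted p = 2.45e-05 and 0.00177). At 6 h and 9 h KO1 stayed lower (0.00187 and 0.000409), and KO2 did not pass (0.996 and 0.993). Over all 4 times with pairs summed, G1/S genes turned lower in the clones (adjusted p = 0.044, 0.618 with an estimated correlation). The snoRNA hosts turned lower without passing (0.399), and the call for the integrated stress response was lost (0.213). In that setting the lowest adjusted p of the 26 lists with an estimated correlation was 0.0722.

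Of 25 neutrophil and granule genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.54, or -0.32 with genes at 0 counts set to their bound; adjusted p = 2.22e-08). Ctsg, the granule protease cathepsin G, had 0 counts in KO2 and 14.37 ± 0.60 CPM in WT, at least 153-fold lower. In KO1 it stood at 21.03 ± 2.27, higher than in WT (adjusted p = 0.000242). In KO1 the list had 9 lower and 5 higher (10 and 5 adjusted over the list alone; median -0.14), a call lost with an estimated correlation (adjusted p = 0.052); in KO2 14 were lower and 2 higher (15 and 2 adjusted over the list alone; median -0.78, adjusted p = 5.4e-05 with an estimated correlation). Of 14 macrophage genes 5 fell and 2 rose (5 and 2 adjusted over the list alone; adjusted p = 0.0226), with Adgre1, the F4/80 antigen, 3.05-fold lower; KO1 alone did not pass (adjusted p = 0.0797). Of 10 stromal genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.00209, median -2.48, or -1.30 with bounds). Bgn and Fn1, matrix genes with 2.34 and 1.42 CPM in WT, had 0 counts in both clones, which makes them at least 49.1-fold and 29.8-fold lower. The stromal difference held against the WT libraries of 0 h only: at 3, 6 and 9 h neither clone passed (adjusted p between 0.475 and 0.996), and over all 4 times the adjusted p was 0.31. Ribosomal protein mRNAs shifted little: 52 of 79 fell and 5 rose (55 and 5 adjusted over the list alone; median -0.07, adjusted p = 6.52e-12). This averaged unlike clones, with a median of 0.00 in KO1 (16 rose and 21 fell, 21 and 22 adjusted over the list alone; adjusted p = 0.91) and -0.12 in KO2 (4 rose and 64 fell, 5 and 66 adjusted over the list alone; adjusted p = 7.7e-28). Mitochondrially encoded mRNAs gave 8 of 13 lower (8 adjusted over the list alone; median -0.28, adjusted p = 1.4e-12), with a median of -0.05 in KO1, where the call was lost with an estimated correlation (adjusted p = 0.239), and -0.47 in KO2 (adjusted p = 0.0211 with an estimated correlation).

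The 11 lists that did not pass camera had adjusted p between 0.0593 and 0.648. Members that rose and fell numbered 14 and 6 of 40 for G2/M, 1 and 3 of 12 for histones, 8 and 10 of 35 for short-lived regulatory mRNAs, and 7 and 11 of 30 for IL-3 and STAT5 response. They numbered 10 and 3 of 27 for stem and progenitor genes, 1 and 6 of 20 for mast cell genes, and 4 and 4 of 21 for erythroid and megakaryocyte genes. For chaperones of the unfolded protein response they were 10 and 6 of 24, for nuclear-encoded oxidative phosphorylation 8 and 17 of 73, and for apoptosis regulators 10 and 3 of 30. Of 9 lymphoid genes 2 fell, Nkg7 and Cd79b. Adjusted over the list alone, the counts were 15 and 7, 1 and 3, 9 and 10, 7 and 11, 10 and 3, 1 and 6, 5 and 4, 11 and 6, 8 and 17, 10 and 3, and 2. Some of these averaged unlike clones. In KO2 nuclear-encoded oxidative phosphorylation passed lower (31 fell and 3 rose, 35 and 3 adjusted over the list alone; adjusted p = 0.00016), and KO1 did not pass (5 fell and 14 rose, the same adjusted over the list alone; adjusted p = 0.783). Stem and progenitor genes (12 rose and 2 fell, 13 and 2 adjusted over the list alone; adjusted p = 0.000169), erythroid genes (8 and 1, the same adjusted over the list alone; 0.000564) and G2/M genes (15 and 3, 15 and 4 adjusted over the list alone; 0.0102) also passed in KO2. In KO1 the IL-3 and STAT5 list passed lower (15 fell and 5 rose, the same adjusted over the list alone; adjusted p = 0.0167). Unfolded protein response chaperones passed higher in KO1 (11 rose and 5 fell, 12 and 5 adjusted over the list alone) and lower in KO2 (4 and 9, 5 and 9 adjusted over the list alone), calls lost with an estimated correlation (adjusted p = 0.052 and 0.072). The median of the short-lived list (0.02) was positive where its mean (-0.18) and test pointed down. The mean of the stem and progenitor list (-0.03) was negative where its test pointed up, and that of the histones (0.20) positive where its test pointed down. Single genes in these lists included Myc, 1.32-fold higher, Dusp5, a MAP kinase phosphatase 4.08-fold lower, and Pim2, a survival kinase 1.40-fold lower.

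**Figure D2:**
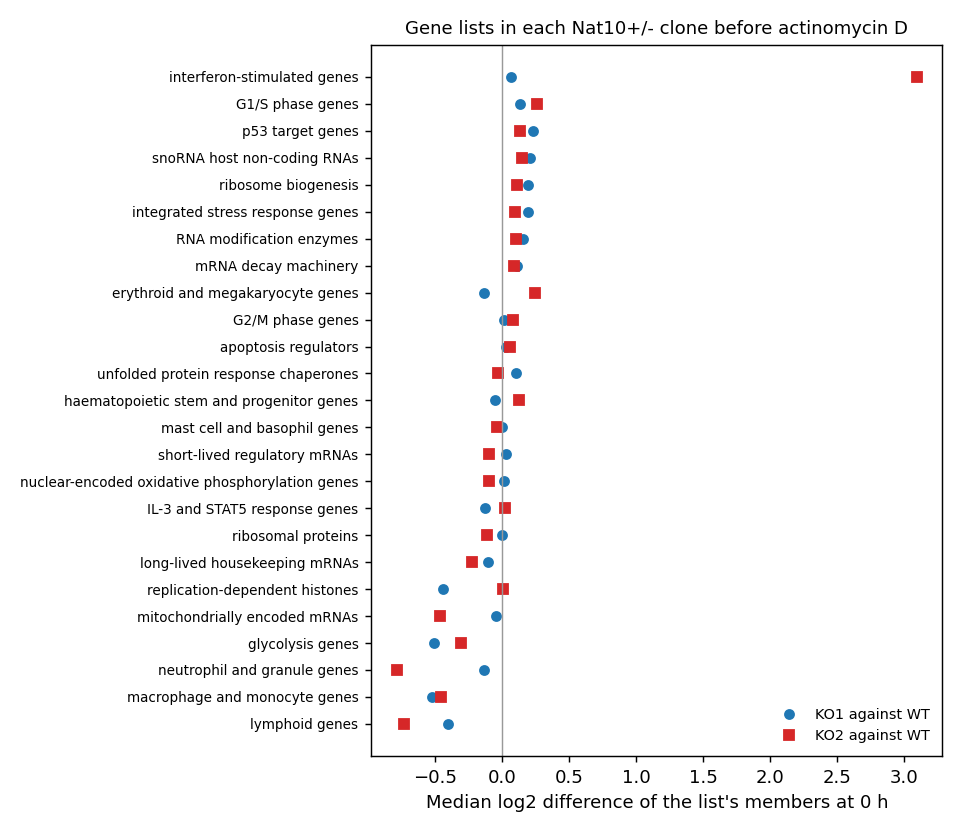
Median log2 difference from WT at 0 h of the tested members of each list, KO1 as circles and KO2 as squares; the stromal list is not drawn. The interferon-stimulated list lay at 3.09 in KO2 and 0.07 in KO1, and the glycolysis list lay below 0 in both clones.

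An interferon-type signature set KO2 apart from KO1. All 36 tested interferon-stimulated genes were higher in KO2 than in WT (36 adjusted over the list alone; median log2 3.09, camera adjusted p = 3.38e-80, 6.27e-09 with an estimated correlation). In KO1 8 rose and 6 fell (8 and 6 adjusted over the list alone; median 0.07, test direction down, adjusted p = 0.91). The difference between the clones was tested directly, and all 36 were higher in KO2 than in KO1 (36 adjusted over the list alone; median 2.93, adjusted p = 9.36e-130). Rtp4 (chromosome 16, 23339041 to 23432972), an interferon-induced chaperone of receptors, had 2062 counts over the KO2 libraries of 0 h, 0 in KO1 and 2 in WT. It was at least 666-fold higher in KO2 than in KO1. Mx2, a GTPase that restricts viruses, stood at 0.41 CPM in WT, 1.06 ± 0.37 in KO1 and 56.72 ± 0.29 in KO2. Usp18, a brake on interferon receptor signalling, stood at 11.98 ± 0.14, 15.39 ± 1.01 and 216.5 ± 0.19. Mx1 was 161-fold and Ifi203 232-fold higher in KO2 than in KO1 by their counts, and Apol9b 138-fold.

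The list of both clones against WT (31 of 36 higher, 32 adjusted over the list alone; median 1.62) therefore averaged unlike clones. KO2 kept a higher median than WT at 3 h (1.54), 6 h (1.46) and 9 h (1.49), with 31, 32 and 34 members higher. Markers of macrophages and monocytes did not move with it: their median, KO2 against KO1, was -0.17 (1 rose and 4 fell of 14, 1 and 5 adjusted over the list alone; camera adjusted p = 0.0557). In all, 2722 genes differed between KO2 and KO1 at 0 h, 1178 higher in KO2. Ctsg was at least 225-fold and Mid1ip1 at least 102-fold lower in KO2 than in KO1, Lyz2 4.59-fold and Itgb4, an integrin subunit, 4.19-fold lower. Over all 4 times with pairs summed, 455 genes differed between the clones.

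**Figure D3:**
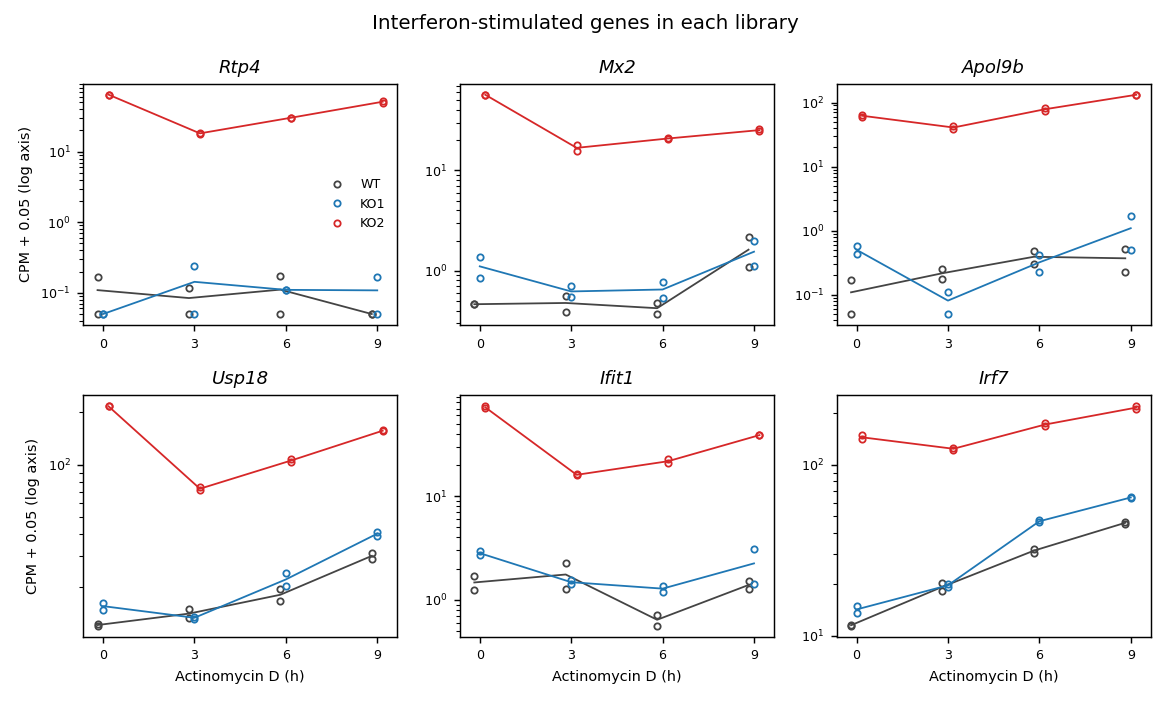
CPM plus 0.05 (log axis) of 6 interferon-stimulated genes against hours of actinomycin D, 1 point per library with lines through the means. KO2 lay above WT and KO1 at each time, with Mx2 at 56.72 CPM in KO2 and 0.41 in WT at 0 h.

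Actinomycin D changed most of the measured transcriptome in WT. Ribosomal protein mRNAs took a larger share of the libraries at 9 h, and those of stem and progenitor genes and of the integrated stress response a smaller one. Fut8 (chromosome 12, 77284899 to 77523112), a fucosyltransferase, fell from 485.1 ± 13.2 CPM at 0 h to 48.19 ± 1.41 at 3 h and 10.1 ± 0.10 at 9 h (SD, n = 2). Myc fell from 348.1 ± 6.64 to 19.03 ± 1.1, which is 18.3-fold. Pmaip1, the p53 target that encodes the death factor Noxa, rose from 30.14 ± 2.10 to 425.1 ± 6.51, 14.1-fold.

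At 9 h 13213 of 16167 genes differed from 0 h in WT (edgeR), 6988 higher and 6225 lower. At 3 h the number was 11666 and at 6 h 12790. These are shares of the library, not amounts per cell. With spike-in totals as the scale 2579 genes in WT, 4583 in KO1 and 2066 in KO2 were called at least 2-fold higher at 9 h. With spike-in totals as the scale 12444 genes were called, 3416 higher and 9028 lower, and the median of all genes moved from 0.125 to -0.70 (log2). Other large falls at 9 h were Arl15 (log2 -6.82, SE 0.25, adjusted p = 2.98e-47), a small GTPase, Inpp4b (-5.66, SE 0.08), a phosphoinositide phosphatase, and Atrnl1 (-5.29, SE 0.11). Large rises were Nectin4, an adhesion molecule, from 0.44 ± 0.21 to 85.04 ± 3.28 CPM, and Zscan10, a zinc-finger factor with 1 count at 0 h and 1027 at 9 h (1010-fold, 181 to 39900 by counting). Slc29a4, a transporter, had 0 counts at 0 h and was at least 111-fold higher at 9 h. Ankrd65 was 169-fold higher (46.5 to 1400).

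**Figure D4:**
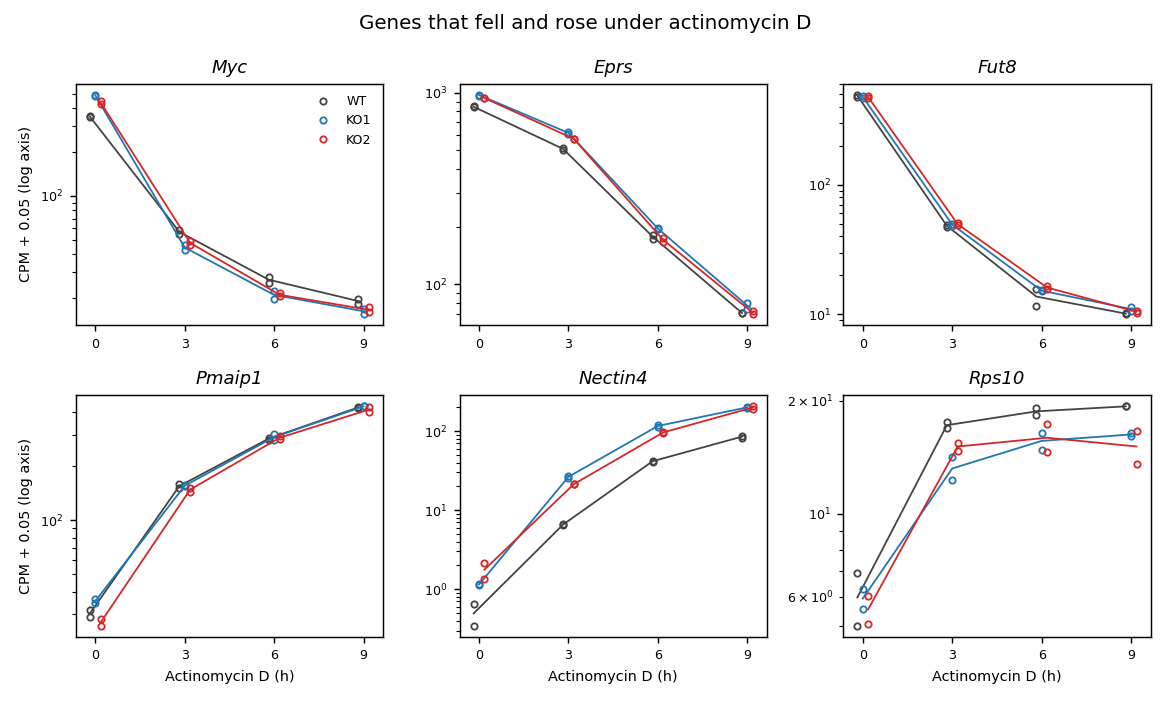
CPM plus 0.05 (log axis) of 6 genes against hours of actinomycin D, 1 point per library with lines through the means. In WT, Myc went from 348.1 to 19.03, Fut8 from 485.1 to 10.1 and Pmaip1 from 30.14 to 425.1.

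Of the 26 lists, 12 passed camera in WT at 9 h against 0 h. Ribosomal protein mRNAs gave 77 of 79 higher (77 adjusted over the list alone; median 0.69, adjusted p = 8.67e-37). Their median turned to -0.14 with spike-in scaling, with 6 higher and 18 lower, still above the median of all genes. Of p53 targets 30 of 37 rose and 5 fell (30 and 5 adjusted over the list alone; median 1.34, 0.51 with spike-ins; adjusted p = 1.55e-08). Cd80, a costimulatory ligand, was 21.8-fold higher, and Pvt1, a non-coding neighbour of Myc, 4.28-fold lower. The integrated stress response list had 28 of 32 members lower and 2 higher (28 and 2 adjusted over the list alone; median -1.74, -2.57 with spike-ins; adjusted p = 1.93e-12). For ribosome biogenesis 53 of 73 fell and 12 rose (53 and 12 adjusted over the list alone; median -0.62, -1.44 with spike-ins; adjusted p = 7.32e-06), Ddx10, a helicase, by 8.82-fold. Stem and progenitor genes fell in 19 of 27 cases and rose in 6 (19 and 6 adjusted over the list alone; median -1.26, -2.09 with spike-ins; adjusted p = 4.55e-05). Runx1 was 21.6-fold and Fli1 19.0-fold lower, both regulators of blood stem cells. Nuclear-encoded oxidative phosphorylation gave 48 of 73 higher and 16 lower (48 and 16 adjusted over the list alone; median 0.43, adjusted p = 0.000514), and its median turned to -0.39 with spike-ins. Erythroid and megakaryocyte genes gave 14 of 21 higher and 3 lower (median 1.04, 0.23 with spike-ins; adjusted p = 0.00554), and interferon-stimulated genes 21 of 36 higher and 7 lower (median 0.81, 0.01 with spike-ins, where 12 were higher and 11 lower; adjusted p = 0.00688). For mRNA decay machinery 30 of 48 fell and 15 rose (median -0.49, -1.31 with spike-ins; adjusted p = 0.022). Counts of these 3 lists were the same adjusted over the list alone.

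The calls for long-lived mRNAs (24 of 40 higher, 13 lower; adjusted p = 0.0586 with an estimated correlation), macrophage genes (11 of 14 higher, 2 lower; adjusted p = 0.0579 with an estimated correlation) and mitochondrially encoded mRNAs (10 of 13 higher, 1 lower; adjusted p = 0.423 with an estimated correlation) were lost with the estimated correlation. Their counts were the same adjusted over the list alone. With spike-in totals long-lived mRNAs turned to 6 higher and 26 lower (median -0.44) and mitochondrially encoded mRNAs to 2 higher and 7 lower (median -0.44), while macrophage genes gave 7 higher and 3 lower (median 0.75). Actb and Gnb1, members of the long-lived list, fell 2.23-fold and 6.39-fold.

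The comparison at the centre of the series, the course of mRNA levels over time in the clones against WT, gave few genes when each course was fitted as a straight line. The clearest cases started lower in the clones at 0 h and ended near or above the WT level at 9 h. Stom (chromosome 2, 35203998 to 35226988), the membrane protein stomatin, went from 2.40 to 19.81 CPM in WT, from 0.71 to 23.48 in KO1 and from 0.53 to 17.33 in KO2. Pacsin1 (chromosome 17, 27874483 to 27930456), an endocytic adaptor, stayed near 7 CPM in WT (7.04 at 0 h, 6.89 at 9 h) and rose from 2.16 to 7.28 in KO1 and from 2.03 to 9.16 in KO2. Fam234a stood at 30.02 CPM at 0 h and 31.22 at 9 h in WT, and rose from 19.90 to 42.37 in KO1 and from 18.14 to 41.16 in KO2.

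Over both clones, 84 of 16167 genes had a slope different from that of WT (edgeR), 69 higher (slower relative loss or faster relative gain) and 15 lower. KO1 alone gave 29 (27 higher) and KO2 alone 31 (24 higher), and 15 were called in both clones in the same direction (14 higher). In a simulation with a common slope in all genotypes, the clones shared none. Each simulated library varied on its own, without deviations shared by a pair. It therefore does not show that the 15 shared calls exceed chance. The slope differences of the clones correlated across genes at r = 0.682, against 0.499 in that simulation, with a covariance of 0.00554 against 0.00387. The slope differences were 0.23 log2 units per hour for Stom (SE 0.04, adjusted p = 0.00375) and 0.23 for Pacsin1 (SE 0.04, adjusted p = 0.00295). They were 0.16 for Cacnb3, a calcium channel subunit, 0.15 for Kank2, 0.14 for Tle2, a corepressor, 0.14 for Ltk, a receptor kinase, 0.12 for Slc27a1, a fatty acid transporter, and 0.12 for Fam234a (SE 0.01, adjusted p = 0.00067). Cep83os, a non-coding RNA, was the gene lower in both clones at -0.14 (SE 0.02, adjusted p = 0.00292). It went from 23.40 to 7.52 CPM in KO1 and from 18.13 to 15.42 in WT. Against WT, KO2 had lower slopes for Irf7, Serpina3f and Ttc39b and a higher one for Vsir. Of these only Irf7 differed between the clones by the direct test (-0.19, adjusted p = 0.00411). Nat10 itself differed by -0.03 (adjusted p = 0.333).

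These calls were fragile. Without WT replicate 1 the number for both clones was 0 (724 genes at an unadjusted p under 0.05, edgeR), and without WT replicate 2 it was 1. Leaving out replicate 1 or 2 of KO1 left 7 or 8, and of KO2 14 or 13. DESeq2 called 290. With RLE scaling 104 genes were called over both clones (95 higher) and 27 in KO2 (25 higher). Fitted instead as the change from 0 h to 9 h, an alternative planned in advance whose spread comes only from the replicate pairs, 4874 genes differed, 2608 higher and 2266 lower. All 84 straight-line calls were among them with the same sign.

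Gene groups differed between genotypes in the change from 0 h to 9 h, where the spread again comes only from the replicate pairs. Culture or harvest effects shared by a pair cannot be separated from genotype and time in these values. For ribosomal protein mRNAs 77 of 79 changed to a lower level in the clones relative to WT (77 adjusted over the list alone; median -0.31, camera adjusted p = 2.6e-124, 4.3e-05 with an estimated correlation). Rpl3 went from 1074 to 1212 CPM in WT, and from 1141 to 876 in KO1 and 1047 to 797.4 in KO2. Glycolysis genes gave 16 of 25 higher and 2 lower (17 and 4 adjusted over the list alone; median 0.34, adjusted p = 2.34e-17). Bnip3 fell from 119.7 to 88.42 CPM in WT and rose from 45.63 to 96.76 in KO1. Of 15 snoRNA host RNAs 13 were lower (13 adjusted over the list alone; median -0.41, adjusted p = 1.48e-07), and of 40 G1/S genes 28 (29 adjusted over the list alone; median -0.32, adjusted p = 9.91e-13).

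On the straight-line slopes, 9 lists passed camera, 2 higher and 7 lower. The snoRNA hosts (median -0.04 log2 per hour, adjusted p = 0.00887 with an estimated correlation) were the list that held, with Snhg17 at -0.08 (SE 0.02, adjusted p = 0.0455) as 1 called member of 15 (1 adjusted over the list alone). The other calls were lost. Their adjusted p with an estimated correlation was 0.654 for ribosomal proteins, 0.623 for ribosome biogenesis, 0.223 for G1/S, 0.431 for stem and progenitor genes, 0.0568 for stromal genes, 0.431 for the integrated stress response, 0.623 for interferon-stimulated genes and 0.101 for glycolysis. Called members were 3 of 25 for glycolysis (7 adjusted over the list alone), Bnip3 and Egln3 among them, Rrp12 for ribosome biogenesis and Tal1, a master regulator of blood formation, for stem and progenitor genes. The change from 0 h to 9 h passed for 13 lists, 12 with an estimated correlation.

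**Figure D5:**
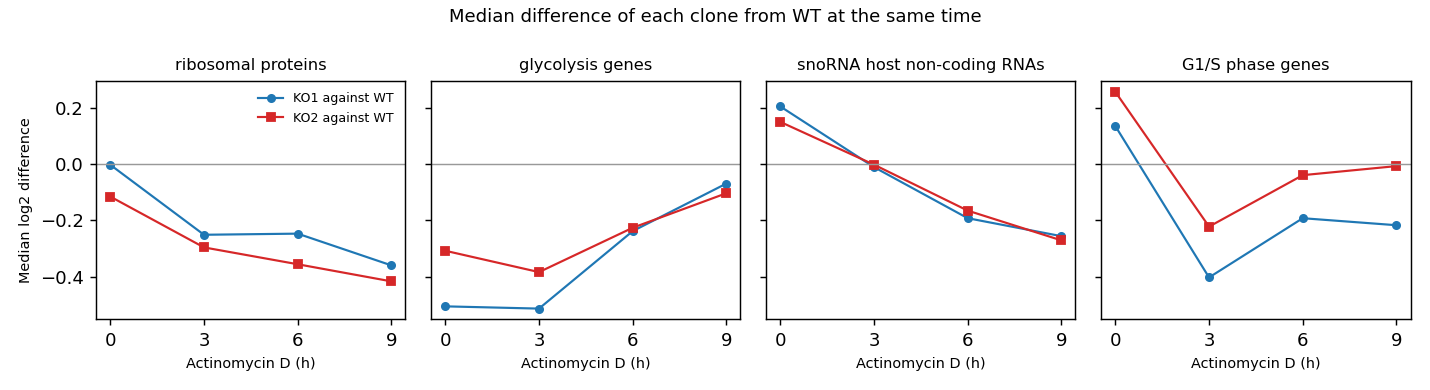
Median log2 difference of each clone from WT at the same hour for 4 lists, KO1 as circles and KO2 as squares. Ribosomal protein mRNAs went from 0.00 (KO1) and -0.12 (KO2) at 0 h to -0.36 and -0.42 at 9 h, while glycolysis genes went from -0.51 and -0.31 to -0.07 and -0.10.

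The last comparison asked whether the typical transcript had another slope in the clones. The median slope was -0.0187 ± 0.000745 log2 units per hour in WT (SD, n = 2 series), -0.0181 ± 0.00107 in KO1 and -0.0194 ± 0.000338 in KO2. The KO series differed from the WT series by -4.44e-05 (exact permutation test, p = 1, smallest possible p = 0.133). TMM sets the average transcript near 0 and the test has few splits, so these values do not show that stability was alike. With spike-in totals the median slopes were -0.112, -0.0203 and -0.148, which put the clones on opposite sides of WT (exact p = 0.8). With RLE scaling the KO series differed from WT by 0.00403, and without the 0 h libraries by -0.00408 (exact p = 0.133 for each, the smallest possible).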

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

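The tests of shared reads among interferon-stimulated genes and both tests of spike-in carry-over were chosen after related values had been seen; the carry-over tests use a criterion set after a first one had come out undecided.

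The difference from WT at 0 h was not the same in the clones for 2722 genes, by the direct test of KO2 against KO1. For slopes over time that test called 2 genes, Irf7 (-0.188 log2 units per hour) and Sp100 (-0.111), both named because they are the whole set. Of the fixed lists, 16 differed between the clones at 0 h by camera with the preset and with an estimated correlation. The medians of KO2 against KO1 were 2.93 for interferon-stimulated genes, 0.357 for erythroid and megakaryocyte genes, 0.174 for glycolysis, 0.127 for G1/S, 0.118 for stem and progenitor genes, 0.0668 for IL-3 and STAT5 response and 0.0606 for G2/M. They were -0.472 for mitochondrially encoded mRNAs, -0.304 for neutrophil genes, -0.12 for ribosomal proteins, -0.119 for nuclear-encoded oxidative phosphorylation, -0.115 for chaperones of the unfolded protein response, -0.108 for snoRNA hosts, -0.0679 for ribosome biogenesis, -0.0478 for the integrated stress response and -0.039 for p53 targets. The spike-ins, which enter no main comparison, had a CPM in KO2 at 0 h that was 46.3 times that in WT.

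For the interferon-stimulated genes, 3 technical explanations were tested. A change of the 0 h preparations alone is argued against by the later libraries, where the lowest median of KO2 against WT was 1.46. Reads shared within gene families are argued against by 20 members without near-identical relatives, of which 18 were tested and 18 were higher in KO2 than in KO1, with a median of 2.01. Macrophages or monocytes in the KO2 cultures would have raised their markers, whose median against KO1 was -0.17. A hypothesis that stays open is an interferon-type response in clone KO2 that may have nothing to do with the shared genotype label, since KO1 lacks it; with 1 clone of each kind, neither the cause nor its link to Nat10 was tested.

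For the low spike-in counts of WT, a smaller amount of the same mix would give WT the shares of KO2 across spike-in transcripts. Over 20 transcripts these shares correlated at r = 0.994. Carry-over of reads from KO2 would also give like shares, so this value does not tell these explanations apart. Whether WT received any spike-in, or reads carried over from other libraries, was tested by asking if genes abundant in the clones had fewer WT counts than the same carry-over would bring. Against the KO2 libraries of 0 h, 4 genes did by an exact binomial test (6 by a first criterion that asked for 10), among them Rtp4 (2 counts where 46.8 would be brought) and Ifi203 (4 where 54.4 would be), and against all KO libraries 2 did, Apol9b (2 where 23 would be brought) and Nectin4 (15 where 48.7 would be), which argues against both sources. Of 8 KO groups tried as the only source 7 had such a gene, while the KO1 libraries of 0 h had 0 and stay open. Sources mixed in unequal shares were not tested. No biological explanation was tested, since the mix was added after extraction.

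For the gap between 84 slope differences and 4874 differences in the change from 0 h to 9 h, curved time courses common to all genotypes are consistent with the 3526 genes called once a term for each time was shared by the genotypes; with pairs summed that count was 537, against 0 for straight lines, and lies under the 1000 set in advance for the unsummed fit. Chance values that differ gene by gene at 0 h and 9 h are argued against by the change from 3 h to 6 h. That change, from other libraries, had the same sign in 70.2% of the called genes. Genes can move together, so this share does not argue against a chance shift common to many genes. A weaker response of all genes in the clones is argued against by the spread of the changes, whose ratio to WT was 1.01 or more. Genotype differences in the course of many mRNAs stay open as a hypothesis, but so do culture or harvest effects shared by both libraries of a pair, which this design cannot separate from genotype and time.

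Chance could not be excluded for the slope counts when genotype labels were permuted within each time over 100 splits. Splits with a count as large, the real one included, numbered 9 for KO1 (real count 29, highest other 646), 15 for KO2 (31, highest other 136), 7 for both clones (84, highest other 421) and 43 for the lists (9, highest other 15). Of the draws, 49 kept the pairs together, and every other split with as many genes was among these. They numbered 8 for KO1, 14 for KO2 and 6 for both clones. Counts out of 100 therefore understate how often such splits arise when pairs are kept. Where single libraries were permuted the highest gene counts were 1, 1 and 6, so the gene counts point to a structure of the samples in which each pair stands apart from other pairs. For the lists both kinds of split reached 15, so that reading does not extend to them.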

How the results depend on the processing

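Among the settings below, summed pairs, spike-in totals, the shared time course and the difference over all 4 times were chosen after the data had been seen, as were the other time models for the lists. Of 135 alternative values of the main results, 80 were taken as kept. For counts this asked only for a total within 1.5 times the main one, not for the same genes or directions. With spike-in totals the count of WT at 9 h was taken as kept, though 1177 of its calls turned. Nat10 had to keep its direction and its side of the threshold, and the median slope to stay within the spread of the series. The named genes kept direction and call in 2565 of 2948 cases, lost the call in 370 and turned in 13. For those that moved, the cause was not tested, except that summed pairs and left-out replicates have fewer samples. The 0 h and WT counts stayed within 1.5 times under each alternative but 1. The genes were less stable than the counts over all 4 times with pairs summed. There 1476 of 4416 calls for KO1, 1986 of 4747 for KO2 and 2161 of 5102 for both kept call and direction. In the opposite direction 21, 18 and 59 were called. Leaving out 1 library gave 3298 to 4423 genes for KO1, 3666 to 4698 for KO2, 3738 to 4726 for both, 1859 to 2712 for KO2 against KO1 and 12519 to 12570 for WT at 9 h; Nat10 stayed between -0.203 and -0.127. Over all 4 times with pairs summed, KO2 against KO1 gave 455.

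The slope counts for KO1, KO2 and both clones (29, 31 and 84) were 4, 5 and 17 with no filter, 184, 169 and 290 with DESeq2, 4386, 4192 and 4874 for 9 h against 0 h, 2957, 2751 and 3526 with the shared time course, and 158, 189 and 537 with that course and summed pairs. They were 12 and 2 for the single clones without the 9 h libraries, and 273, 282 and 584 without the 0 h libraries. Leaving out a replicate gave 0 to 9, 0 to 6 and 0 to 14. With spike-in totals they were 2402, 0 (1254 genes at an unadjusted p under 0.05, edgeR) and 18. Straight lines on summed pairs gave 0, 0 and 0 (178, 181 and 245 at an unadjusted p under 0.05, edgeR). With the replicate number as a block the slope counts were 15, 7 and 43, and those at 0 h 4467, 4781 and 5178. Same-numbered libraries did not deviate together (correlations -0.0229 to 0.152, 4 of 66 over 0.1), so the numbers do not pair them.

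Over all 4 times 11 of the 15 lists of 0 h kept their call with the preset correlation and none with an estimated one (lowest adjusted p = 0.0722); G1/S (adjusted p = 0.044) and snoRNA hosts (0.399) turned, and the integrated stress response (0.213) and stromal genes (0.31) lost it. Lists past 0.05 at 0 h rose from 15 to 25 with fry, and those for slopes fell from 9 to 1 with an estimated correlation and 3 with fry. The difference of median slopes was 0.0281 with spike-in totals, -0.000874 at a minimum of 1 CPM, -0.00207 without 9 h and -0.00408 without 0 h. Genes that turned over all 4 times were Exoc3l2 (0.717 over both clones, 0.817 in KO1), Sertad1 (0.155), Ndc80 (-0.00399), Hist1h2af (-0.399), Myc (-0.0981), Klf10 (-0.255), Cebpd (-0.0491), Itga2b (-0.00453), Lgmn (-0.0223) and Cebpb (-0.589). With spike-in totals Rrp12 turned in the KO1 slope (0.0113) and Ddit4 in WT at 9 h (-0.294). Depth limits genes near the floor, such as Exoc3l2 with 5 and 14 counts.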

Other observations

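The heat-shock chaperone and hypoxia lists were written after values at 0 h and 3 h had been seen, and the test of all rising genes was added after the test on chaperones had come out undecided.

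Cytosolic chaperones of the heat-shock response were higher at 3 h of actinomycin D than at 0 h and at 9 h in every genotype. In WT 14 of 18 tested members rose from 0 h to 3 h and 2 fell (median log2 0.964), in KO1 15 rose (1.04) and in KO2 16 rose (0.944). From 3 h to 9 h the medians were -0.72, -0.956 and -1.01. Hspa8, the constitutive Hsp70, went from 925 CPM at 0 h to 3440 at 3 h and 801 at 9 h in WT, and Hsph1, an Hsp110 chaperone, from 95.6 to 375 and 142. Hsp90aa1 went from 1260 to 3800 and 2620. A candidate explanation is the changed makeup of the libraries alone. With spike-in totals the 3 h medians were 0.881 in KO1, 0.464 in WT and 0.268 in KO2, where those of all genes were -0.0492, -0.365 and -0.545. All lie above 0, but the bound had been set on KO2 at 0.5, so that explanation stays open for the chaperones. For genes that rise under the drug in general, the lowest number still at least 2-fold higher at 9 h with spike-in totals was 2066, in KO2, which argues against scaling as the whole cause.

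Genes of the response to low oxygen outside the glycolysis list were also lower in both clones before the drug. Of 25 tested, 15 fell and 2 rose over both clones (median log2 -0.186). In KO1 alone 10 fell and 2 rose (-0.15), and in KO2 alone 14 fell and 2 rose (-0.195). Fam162a went from 82.9 CPM in WT to 49 in KO1 and 51.1 in KO2, P4ha1, a collagen prolyl hydroxylase, from 77 to 52 and 58.1, and Pdk1, a kinase that limits pyruvate oxidation, from 118 to 84.8 and 98.6. Vegfa (256, 266 and 253) did not pass the test. The list was written after 0 h values had been seen, so its count is no independent evidence.

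One identifier without a name in the table used here, ENSMUSG00000119584 (chromosome 17, 40157244 to 40159092), moved between groups but hardly within pairs. It stood at 11100 and 10900 CPM in the KO2 libraries of 0 h, 7230 and 7230 in KO1 at 3 h, 2900 and 2860 in WT at 0 h, and 1060 and 1050 in KO1 at 6 h. It was chosen after its values were seen.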
